A study of Mus musculus with 5 samples.

How the data were processed

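Small RNA of testis was measured in 5 libraries, 2 from wild-type and 3 from Mtdh-/- mice. Per the labels' protocols, RNA was extracted from frozen testes with the mirVana kit and libraries were made with an Illumina TruSeq kit. The submitters' processing notes name Novoalign 2.07.11. The genome build, adapter trimming and counting rules are not given in the sources used here. Per the file headers, the authors deposited raw tag counts per mature miRNA and precursor, with a count of all isoforms, a count of the most abundant sequence and a count of the exact mature sequence. In the deposited counts the smallest value above 0 was 2, and a blank cell was read as 0. A second deposited sheet held the same tags scaled by the authors with 1 factor per library and rounded to whole numbers, a normalized score and not counts. The fold ratio of each miRNA in the authors' tables was the ratio of normalized tags of the most abundant sequence with 10 added to each value, per the file headers. The p-value columns of the authors' group tables come from a test that is not given in the sources used here. For piRNAs the authors deposited, per the file headers, normalized tag values (a signal whose scaling is not given in the sources used here) and a signed fold score with 10 added to each value, only for piRNAs past a fold threshold. Headers of the miRNA tables state thresholds of 1.5 and 0.67, while the miRNAs listed for single libraries had ratios of at least 2 or at most 0.5. A further 191 columns of per-library values in these files were not used.

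The sheet of miRNA counts held 846 lines for 736 mature miRNAs. For a mature miRNA listed under several precursors the line with the largest total was kept, which left out 110 lines. A further 19 miRNAs whose most abundant sequence was identical to that of another were joined to it, leaving 717. The counts of all isoforms were used. Groups were taken from the genotype in the labels. The design, the lists, the naming rule and the main alternatives were chosen before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust, TMM scaling, filterByExpr on genotype), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Mtdh-/- minus wild type, with SE taken from the fold change and the F statistic. CPM are counts scaled to each library's total of miRNA counts.

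The 20 lists of miRNAs covered germ-cell stages (the miR-34 and miR-449 family, the X-linked cluster, miR-17-92 and paralogs, pluripotency clusters, spermatogonial and spermatid miRNAs), let-7 with miR-98, and Sertoli cells. They also covered blood, endothelium, smooth muscle and stroma, striated muscle, epithelium and neural cells. The remaining lists were the Dlk1-Dio3 and Sfmbt2 clusters, NF-kB responsive miRNAs, miRNAs reported to target MTDH in human cells, and the miR-30 and miR-15/16 families. Some miRNAs, such as miR-21a, miR-9, miR-30a and miR-145a, are in 2 lists. Lists with at least 5 tested members, 13 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between members, adjusted over the lists.

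The named miRNAs were chosen by a rule. It took, in each direction, up to 12 miRNAs past the threshold with a mean of at least 10 CPM and no overlap between genotypes, by fold change. Where fewer passed, it was filled to 12 by the smallest unadjusted p among the others with no overlap. It added the 5 with the highest mean CPM and the 3 most abundant members of each list. Of the piRNAs listed in 1 direction in all 3 tables, it took the 5 in each direction with the largest smallest fold. miR-17-3p, miR-145a-5p, miR-199a-5p and miR-214-3p fall outside the rule and were named after their values were seen, as were miR-191-3p, miR-883b-5p, miR-425 and miR-470-3p in the closing section.

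Shares of counts have 95% Wilson intervals, and the limit for an uncounted miRNA is 3 counts of the library. Shares were compared with a two-sided exact permutation test over the 10 splits of 5 libraries into 2 and 3. Counts of every pair of libraries differed beyond counting noise (chi-square per degree of freedom 52.1 for wild type 1 with Mtdh-/- 3 and 206 to 358 for the other pairs), so no library was counted as a second deposit of another. Separate preparations from 1 RNA sample would differ in this way too and were not tested for. The edgeR test was tried first on simulated counts of the same libraries with 200 changed miRNAs, and the list test on simulated log2 values with normal noise (SD 1) and 1 list, let-7, shifted by 1. With a biological coefficient of variation of 0.2 the edgeR test recovered 99.1% of 4-fold changes and 100% of 16-fold changes, and with 0.7 it recovered 8.67% and 85.2%. Without changes it made 0.15 false calls per run at a coefficient of 0.7. Over 50 simulated runs of 246 miRNAs the list test found the shifted list in 74% and called an unshifted list at an unadjusted p under 0.05 in 3.83%. The noise was independent between members. In the real libraries the estimated correlation between members was 0.344 for let-7 and -0.00553 for the X-linked cluster. These simulated shares therefore do not carry over to lists with correlated members, such as let-7.

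The authors' lists were intersected by name. Overlaps that shared controls give by themselves were simulated 1000 times, for miRNAs with unchanged libraries against the same controls and for piRNAs by drawing lists within classes of similar wild-type values. The alternatives were RLE and upper-quartile scaling, library totals, scaling without the 10 most abundant miRNAs, DESeq2 1.42.0, limma on the authors' normalized values (pseudocount 1), no filter, a filter of 10 CPM in 2 libraries, no robust fit, leaving out each library, and a replicate block. Further ones were an adjusted p under 0.1, an estimated correlation, fry, and other fold limits for the authors' lists. Counts of the most abundant sequence, counts of the exact mature sequence and a block by library similarity were added after seeing the data. Sequences of the named miRNAs were matched exactly to the miRNA hairpins, and those of the named piRNAs to the transcripts, of GENCODE M21 (GRCm38), with positions of hairpins from its annotation, and miR-5109 and miR-1194 were not placed. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.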

Results

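Small RNAs were sequenced from the testes of C57BL/6 mice aged 6 months. The study compared miRNAs and piRNAs of wild-type mice with those of Mtdh-/- mice, which lack exon 3 of Mtdh, the gene of metadherin. There were 2 wild-type libraries and 3 Mtdh-/- libraries. Counts of miRNAs totalled 198640 and 474839 in wild type 1 and 2, and 720259, 118475 and 258433 in Mtdh-/- 1, 2 and 3. The libraries held 308, 420, 423, 305 and 349 miRNAs in that order. A miRNA without counts could still have been present at up to 15.1, 6.32, 4.17, 25.3 and 11.6 CPM (counts scaled to a common library total), the level of 3 counts in each library. Mtdh itself is not a miRNA, so the knockout label was not checked by these files. Nothing beyond the labels says that the libraries came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical.

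miR-10b-5p was the most abundant miRNA of the testis, with 289770 ± 112795 CPM in wild type (SD, n = 2) and 280983 ± 124057 in Mtdh-/- (SD, n = 3). miR-143-3p followed with 93431 ± 35235 CPM in wild type and 96380 ± 13591 in Mtdh-/-. The 10 most abundant miRNAs held 68.8% of the counts in wild type 1 (95% Wilson interval 68.6 to 69.1) and 54.6% in wild type 2 (54.4 to 54.7). They held 70.8% (70.7 to 70.9), 52.5% (52.2 to 52.8) and 63.0% (62.8 to 63.2) in Mtdh-/- 1, 2 and 3. These intervals and the limits for uncounted miRNAs cover counting error only. The mean share was 61.7% ± 10.1 in wild type (SD, n = 2) and 62.1% ± 9.17 in Mtdh-/- (SD, n = 3), a difference of 0.402 percentage points (exact permutation test, two-sided, p = 1, where the smallest possible p is 0.1). Across 246 miRNAs, wild type 1 resembled Mtdh-/- 3 (Pearson r = 0.955, Spearman rho = 0.949) more than wild type 2 (r = 0.870, rho = 0.865), and wild type 2 resembled Mtdh-/- 1 (r = 0.919, rho = 0.915). These correlations are across miRNAs, which are not independent replicates. The first principal component held 42.3% of the variance and placed wild type 1 at -12.8 and Mtdh-/- 3 at -10.6, against 5.55, 8.51 and 9.39 for wild type 2, Mtdh-/- 1 and Mtdh-/- 2. Mtdh-/- 2 stood apart on the second component (34.05%), at -15.1. There wild type 1 and 2 were at -0.514 and 8.34, and Mtdh-/- 1 and 3 at 8.72 and -1.42. Its Pearson r with the other libraries was 0.832 (wild type 1) to 0.845 (Mtdh-/- 1).

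**Figure D1:**
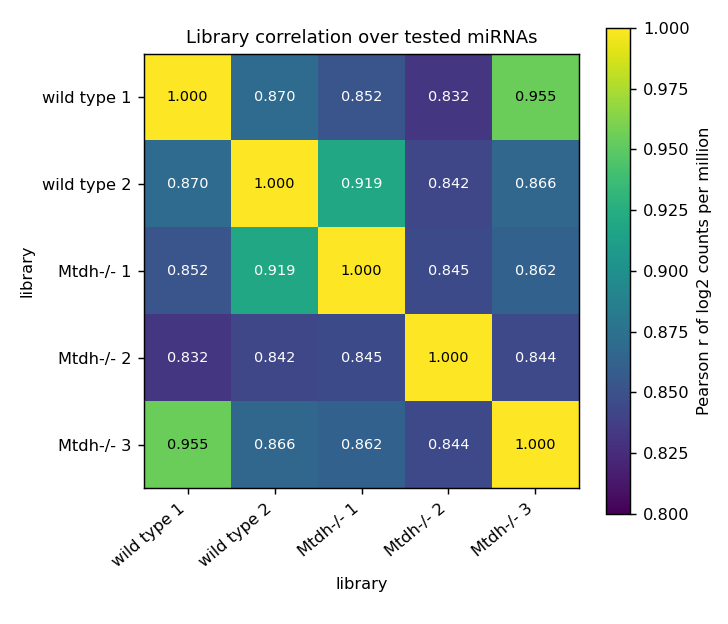
Pearson correlation of log2 CPM between the 5 libraries over 246 miRNAs, with 1 cell per pair of libraries. Wild type 1 and Mtdh-/- 3 reached 0.955, and the pair of wild-type libraries 0.870.

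The first comparison asked which miRNAs differed in the testis without Mtdh. Of the miRNAs with every Mtdh-/- library above both wild-type libraries, miR-100-5p stood at 731 ± 233 CPM in wild type (SD, n = 2) and 3302 ± 2024 in Mtdh-/- (SD, n = 3), a log2 fold change of 2.26 ± 0.87 (SE). Its paralog miR-99a-5p stood at 523 ± 328 and 3358 ± 2703 CPM (2.90 ± 1.21), and miR-22-3p at 6374 ± 1083 and 15987 ± 7986 CPM (1.37 ± 0.57). Of the miRNAs with every Mtdh-/- library below both wild-type libraries, miR-140-5p stood at 260 ± 267 and 51.9 ± 8.51 CPM (-1.95 ± 0.80), and miR-9-5p at 690 ± 320 and 280 ± 54.0 CPM (-1.02 ± 0.60). miR-140-5p rested on wild type 2, since wild type 1 held 70.5 CPM, and its log2 fold change was -0.49 without wild type 2. With 1 library left out, miR-100-5p ranged from 1.77 to 2.98, miR-99a-5p from 1.64 (without Mtdh-/- 1) to 4.15, miR-22-3p from 1.06 to 1.58 and miR-9-5p from -1.50 to -0.77. None of these differences passed the test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 246 miRNAs were higher and 0 were lower in Mtdh-/-, with a lowest adjusted p of 0.867. At an unadjusted p under 0.05 there were 7 miRNAs, where chance gives 12.3. DESeq2 called 0 of 512 miRNAs (19 at an unadjusted p under 0.05), and limma on the authors' normalized values called 0 of 246 (3 at an unadjusted p under 0.05).

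Among the other named miRNAs with every Mtdh-/- library above both wild types, miR-5109 stood at 31.3 ± 5.56 CPM in wild type (SD, n = 2) and 175 ± 63.5 in Mtdh-/- (SD, n = 3), a log2 fold change of 2.70 ± 0.83. It was followed by miR-29c-3p (1.96 ± 0.88), miR-511-3p (1.49 ± 0.88), miR-215-5p (1.30 ± 0.85), let-7g-5p (0.99 ± 0.55) and miR-125b-5p (0.97 ± 0.59). miR-99b-3p (0.84 ± 0.70), miR-130a-3p (0.83 ± 0.54) and miR-181a-2-3p (0.48 ± 0.58) were closest to 0. Without wild type 2, miR-29c-3p was at 3.04, miR-215-5p at 0.72 and miR-181a-2-3p at 0.22. miR-125b-5p was at 0.45 without Mtdh-/- 3, and miR-99b-3p at 0.46 without Mtdh-/- 2. Among those with lower values were miR-141-3p of the epithelial miR-200 family (-1.62 ± 0.84, or -0.34 without wild type 1), miR-30b-3p (-1.61 ± 0.95), miR-192-5p (-0.90 ± 0.64), miR-1194 (-0.84 ± 0.59), miR-184-3p (-0.80 ± 0.65), miR-106b-3p (-0.71 ± 0.51) and miR-25-3p (-0.60 ± 0.51). Without wild type 1 the last 5 were at -0.41, -0.43, -0.49, -0.49 and -0.31, and without Mtdh-/- 3 at -1.45, -1.17, -1.39, -0.99 and -0.97. miR-30b-3p was at -2.50 without Mtdh-/- 1. For miR-5109 and miR-1194 the most abundant counted sequence began with other bases than the mature sequence. That of miR-5109 was also longer than the mature sequence, and neither miRNA was placed on a hairpin. Their values are therefore uncertain as values of miRNAs, and whether the counts come from another RNA was not tested. The most abundant sequences of miR-181a-2-3p, miR-3470b and miR-3471 also began upstream of the mature sequence. That of miR-3471 was longer than its mature sequence. The values of miR-3471 (-2.02 ± 1.12) and miR-3470b (-0.91 ± 0.59) are uncertain, since their sequences match 52 and 45 hairpins of the annotation, and without wild type 1 miR-3470b was at -0.59. The edgeR adjusted p was 0.867 for each of these miRNAs except miR-181a-2-3p (0.918). In all, 12 miRNAs (4.88%) lay higher and 23 (9.35%) lower in every Mtdh-/- library than in both wild-type libraries, where chance gives 10% for each direction. miR-17-3p was counted only in Mtdh-/- 1 (35 counts, 48.6 CPM) and Mtdh-/- 2 (39 counts, 329 CPM). Its Mtdh-/- mean of 126 ± 178 CPM (SD, n = 3) was at least 11.8-fold higher than the mean level of 3 counts per wild-type library, and at least 2.27-fold without Mtdh-/- 2.

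**Figure D2:**
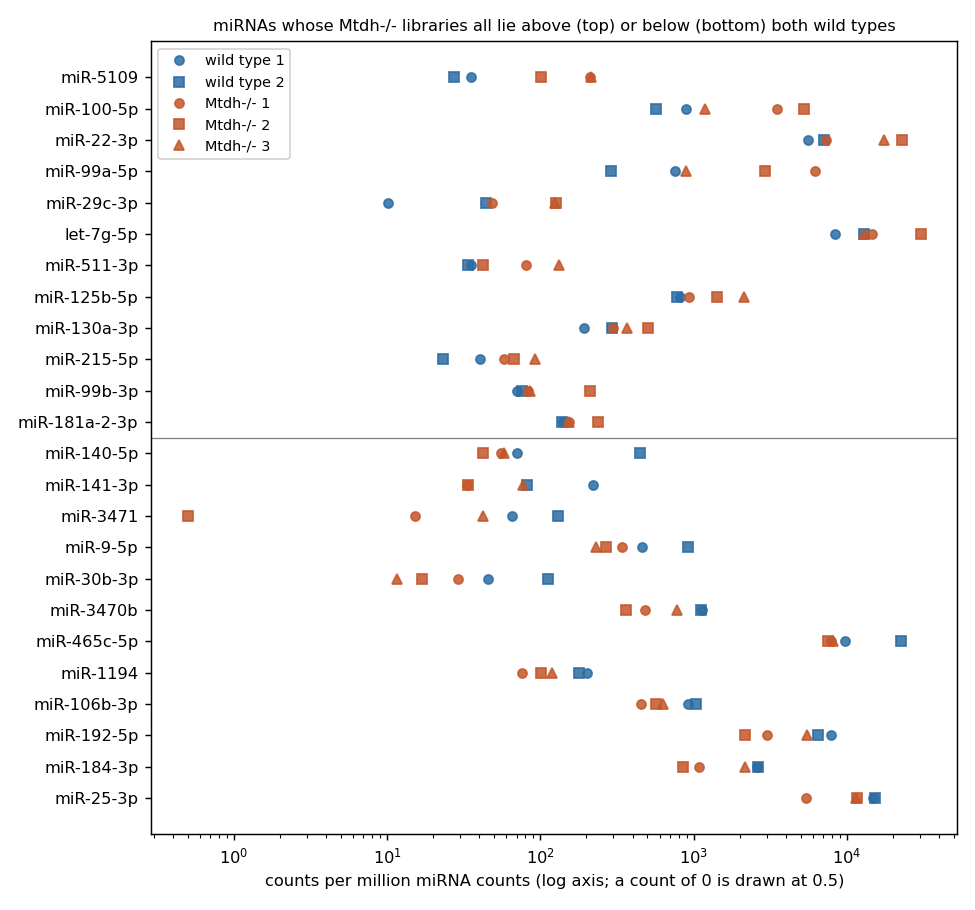
CPM of the 24 named miRNAs with no overlap between genotypes, on a log axis, with 1 point per library and a count of 0 drawn at the far left. In every Mtdh-/- library miR-100-5p lay above both wild-type libraries (lowest 1196 against 896 CPM), and miR-140-5p lay below both (highest 58.0 against 70.5 CPM).

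In GRCm38 with GENCODE M21 annotation, the hairpin of miR-100 lies on chromosome 9 (41531425 to 41531504) in an intron of the noncoding gene 3110039I08Rik, which also holds Mirlet7a-2 (41536716 to 41536811) and Mir125b-1 (41581926 to 41582002). The hairpin of miR-99a is on chromosome 16 (77598936 to 77599000) in an intron of Mir99ahg, and that of miR-22 on chromosome 11 (75463716 to 75463810) in an exon of Mir22hg. Mir140 overlaps an exon of Wwp2 on chromosome 8 (107551244 to 107551313), Mirlet7g lies in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), and Mir25 overlaps an exon of Mcm7 on chromosome 5 (138165321 to 138165404). The spread between libraries was wide, with a biological coefficient of variation of 0.696 and a median SE of 0.77 on the log2 scale. In simulated counts with a coefficient of 0.7, the same test found 8.67% of 4-fold changes and 85.2% of 16-fold changes, so differences of 4-fold were mostly not detectable with these libraries.

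The let-7 family, which increases as cells differentiate, was higher in Mtdh-/-. Of its 11 measured members, 9 had higher and 2 lower values, with a median log2 fold change of 0.99 (camera, adjusted p = 0.0298). The call was lost with an estimated correlation between members of 0.344 (camera, unadjusted p = 0.244, adjusted p = 0.528). let-7f-5p stood at 22117 ± 12461 CPM in wild type (SD, n = 2) and 40950 ± 27937 in Mtdh-/- (SD, n = 3), a log2 fold change of 1.04 ± 0.64, and let-7a-5p at 10078 ± 8087 and 18549 ± 13383 CPM (1.08 ± 0.75). Without Mtdh-/- 2 they were at 0.56 and 0.57, and let-7a-5p was at 0.60 without wild type 1 and 1.90 without wild type 2. The summed family reached 35668 and 87324 CPM in wild type 1 and 2, and 89389, 189627 and 62747 CPM in Mtdh-/- 1, 2 and 3. Between the wild-type libraries alone the members differed by a median of 0.73. The call ended without wild type 1 (median 0.61, adjusted p = 0.403), Mtdh-/- 1 (1.00, 0.130) or Mtdh-/- 2 (0.57, 0.117). Over all settings the adjusted p ranged from 0.00707 to 0.528.

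The X-linked cluster next to Fmr1, a group of testis-enriched miRNAs, was lower in Mtdh-/-. Of its 27 measured miRNAs, 21 had lower and 6 higher values, with a median log2 fold change of -0.41 (camera, adjusted p = 0.0298). This call too was lost when the correlation was estimated (camera, unadjusted p = 0.0503, adjusted p = 0.528). The estimate was -0.00553, below the preset 0.01, so correlation between members did not end this call. miR-470-5p stood at 23674 ± 23662 CPM in wild type (SD, n = 2) and 10536 ± 1142 in Mtdh-/- (SD, n = 3), a log2 fold change of -0.82 ± 0.70. miR-465c-5p stood at 16237 ± 9173 and 7863 ± 291 CPM (-0.80 ± 0.55), miR-881-3p at 14606 ± 8341 and 10663 ± 3037 CPM (-0.48 ± 0.63) and miR-871-3p at 14620 ± 17207 and 12058 ± 13553 CPM (-0.41 ± 1.24). Without wild type 2, miR-465c-5p was at -0.41 and miR-470-5p at 0.52, and without wild type 1, miR-881-3p was at 0.68 and miR-871-3p at 2.67. The summed cluster was 82003 and 111640 CPM in wild type 1 and 2, and 45728, 62123 and 76155 CPM in Mtdh-/- 1, 2 and 3. Without wild type 2 the median was 0.06 (adjusted p = 0.148), and the call also ended without wild type 1 (0.171), Mtdh-/- 1 (0.143) or Mtdh-/- 3 (0.0929). Over all settings the adjusted p ranged from 0.0106 to 0.528. With fry, which asks whether a list moves one way on balance, the adjusted p was 0.427 for both the let-7 family and the X-linked cluster.

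Smooth muscle and stromal miRNAs had higher values in Mtdh-/- for 11 of 11 members, although miR-10b-5p (0.13 ± 0.71), miR-143-3p (0.22 ± 0.44) and miR-10a-5p (0.12 ± 0.83) turned negative with upper-quartile scaling. That scaling shifted the median of all miRNAs by -0.34, and relative to the shift the 3 stayed at 0.16, 0.22 and 0.16. Smaller shifts turned miR-10a-5p negative with RLE scaling and without the 10 most abundant in the scaling, and miR-10b-5p with library totals and limma, each above 0 relative to its shift. Without wild type 2, miR-10b-5p was at -0.39 and miR-10a-5p at -0.66. The median of 0.71 did not pass the test (camera, adjusted p = 0.0676). The list passed with upper-quartile scaling (median 0.33, adjusted p = 0.0291), library totals (0.85, 0.0319), limma on the authors' values (0.85, 0.0412) and counts of the exact mature sequence (0.53, 0.00707), within a range of 0.00707 to 0.887 over all settings. With 1 library left out its median was 0.54 to 2.75, the highest without wild type 1. miR-145a-5p had a log2 fold change of 1.35, and miR-199a-5p (3.68) and miR-214-3p (5.15) each rested on 1 library, with 2210 CPM in Mtdh-/- 1 and 4558 CPM in Mtdh-/- 2. The miR-30 family had lower values for 8 of 10 members (median -0.31, adjusted p = 0.0803), with miR-30a-5p at -0.41 ± 0.44, miR-30e-5p at -0.53 ± 0.58 and miR-30d-5p at 0.00 ± 0.53, and it passed with upper-quartile scaling (-0.66, 0.0348, range over all settings 0.0348 to 0.528). Its median was -0.51 to -0.22 with 1 library left out, the lowest without Mtdh-/- 1. The imprinted Dlk1-Dio3 cluster had higher values for 8 of 10 members (median 0.64, adjusted p = 0.296), among them miR-541-5p (0.98 ± 0.63) and miR-411-5p (0.68 ± 0.55). Its median was 0.04 without Mtdh-/- 3 (adjusted p = 0.842, range over all settings 0.0497 to 0.906). With a block by library similarity, which was read from the same counts and gives p-values that are too small, the smooth muscle (median 0.98), miR-30 (-0.41) and Dlk1-Dio3 (0.78) lists each passed at an adjusted p of 0.0497.

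No germ-cell list other than the X-linked cluster passed the test. The miR-34 and miR-449 family of spermatocytes and spermatids had lower values for 5 of 7 members (median -0.20, camera, adjusted p = 0.298), with miR-449a-5p at -1.21 ± 0.76, miR-34c-5p at -0.20 ± 1.08 and miR-34a-5p at 0.57 ± 0.75. Its median was -0.53 without Mtdh-/- 3 and 0.00 without wild type 2. Spermatogonial miRNAs had higher values for 5 of 8 members (median 0.46, adjusted p = 0.984), with miR-21a-5p at 0.37 ± 0.52, miR-146b-5p at -0.45 ± 0.67 and miR-182-5p at -0.39 ± 0.55. Their median was 0.13 without Mtdh-/- 2, 0.24 without wild type 2, 0.30 without Mtdh-/- 3 and 0.95 without wild type 1. The miR-17-92 group and its paralogs had 6 higher and 7 lower members (adjusted p = 0.984). Its median was -0.02 and its mean 0.66 with miR-17-3p set at its bound, while the test pointed down. With the fitted value of miR-17-3p in place of the bound, the median was 1.21 without wild type 1, 0.21 without wild type 2, and -0.19, -0.24 and -0.18 without Mtdh-/- 1, 2 and 3. Abundant members were miR-25-3p (above), miR-93-5p (-0.02 ± 0.54) and miR-92a-3p (-0.34 ± 0.57). Of the spermatid miRNAs only miR-184-3p was tested (above), and of the pluripotency clusters 0 miRNAs passed the minimum count.

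The miR-15/16 family had higher values for 7 of 9 members (median 0.94, camera, adjusted p = 0.563), with miR-16-5p at 0.36 ± 0.56. In that family miR-195a-5p (2.69 ± 1.47) and miR-15b-5p (1.84 ± 1.39) rested on Mtdh-/- 2, which held 16544 and 11614 CPM against at most 933 and 1251 CPM in any other library. NF-kB responsive miRNAs had higher values for 4 of 7 members (median 0.37, adjusted p = 0.984, test down), with miR-146a-5p at 1.14 ± 0.88. Their median was 0.01 without Mtdh-/- 1, 0.13 without Mtdh-/- 2 and -0.64 with counts of the most abundant sequence. MTDH has been described as an activator of NF-kB. The miRNAs reported to target MTDH in human cells had 3 higher and 4 lower members (median -0.02, mean 0.28, test up, adjusted p = 0.984), with miR-26a-5p at 0.99 ± 1.00, and their median was -0.35 (without Mtdh-/- 2) to 0.06 (without wild type 2) with 1 library left out. Neural miRNAs had 4 higher members and 1 lower (median 0.50, adjusted p = 0.984, test down), with miR-128-3p at 1.30 ± 0.95 and miR-218-5p at 1.32 ± 0.88, and a median of 1.77 without wild type 2. The Sfmbt2 intron cluster had 6 higher and 5 lower members (median 0.39, or -0.14 with library totals, adjusted p = 0.984, test down), with miR-467e-5p at 2.15 ± 1.54, miR-669a-5p at 0.39 ± 1.14 (negative with library totals and limma) and miR-669c-5p at -0.02 ± 0.73 (positive with limma). With library totals, miR-669a-5p and the Sfmbt2 median were at 0.00 relative to the shift of all miRNAs (-0.14). miR-467e-5p rested on Mtdh-/- 1, with 1412 CPM against at most 232 CPM in any other library, and was at -1.07 without it. Without Mtdh-/- 1, miR-669a-5p was at -1.33, miR-26a-5p at -0.12, miR-128-3p at -0.09 and miR-218-5p at 0.43. The Sfmbt2 median was -0.38 without Mtdh-/- 1, -0.05 without wild type 1 and 2.01 without wild type 2, and that of the miR-15/16 family 0.06 without Mtdh-/- 2.

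Lists with under 5 tested members had no list test. The Sertoli cell miR-202 gave -0.42 ± 0.57 for its 5p and 1.03 ± 0.85 for its 3p arm. Of blood cell miRNAs, miR-142-5p was at -0.29 ± 0.73 and miR-451a at 0.83 ± 0.79. Endothelial miR-126 gave 1.29 ± 1.30 for its 3p and -0.67 ± 0.75 for its 5p arm. The 3p arm was at -0.93 without Mtdh-/- 1, and the 5p arm at 0.12 without wild type 1. Of striated muscle miRNAs, miR-1a-3p was at -0.68 ± 0.83 and miR-208b-3p at -0.72 ± 2.04. Of 4 epithelial miRNAs, miR-200a-3p (0.24 ± 0.58), miR-200b-3p (0.08 ± 0.66) and miR-429-3p (0.11 ± 0.71) turned negative with upper-quartile scaling, the latter pair also with library totals and miR-429-3p with limma. Relative to the shift of all miRNAs they stayed at 0.26, 0.11 and 0.15 with upper-quartile scaling and within 0.03 of 0 with the others. In each of the 20 lists, 0 miRNAs were called by edgeR over all miRNAs and 0 when adjusted over the list alone. With 1 library left out, the log2 fold change of 28 of the 43 miRNAs named only as list members or for their abundance changed sign, and a further 14 moved by over 1.5 times. At an unadjusted p under 0.05 there were 2 in the smooth muscle list, 2 in the miR-17-92 group and 1 among the miRNAs reported to target MTDH.

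The authors compared each Mtdh-/- library with the mean of both wild-type libraries. The authors' deposited tables listed 10 miRNAs as lower in all 3 Mtdh-/- libraries and 0 as higher. Ratios of miR-140-5p in the authors' deposited tables were 0.142, 0.180 and 0.137 in Mtdh-/- 1, 2 and 3, those of miR-470-5p 0.468, 0.385 and 0.362, and those of miR-449a-5p 0.455, 0.288 and 0.238. The other 7 in the authors' deposited tables were miR-15a-5p, miR-375-3p, miR-145a-3p, miR-191-3p, miR-212-5p, miR-883b-5p and miR-1195. The authors' deposited tables listed 28, 111 and 44 miRNAs as higher and 86, 87 and 54 as lower in Mtdh-/- 1, 2 and 3. The 3 comparisons share their controls. Libraries redrawn without a genotype difference, controls included, gave 17.5 shared lower miRNAs (95% range 10 to 26) and 7 shared higher miRNAs (2 to 13). Their spread was estimated over both genotypes together, so any genotype difference was counted as spread. The observed 10 lower lay at the low end of its range and the observed 0 higher below its own, so neither overlap exceeded that of the redrawn libraries. Since 0 higher lay outside the range, the redrawn libraries did not match the real ones in full, and what the shared controls gave stays open. The authors' deposited table of all 3 Mtdh-/- libraries as a group listed 9 miRNAs as lower, with p-values up to 0.0401 from a test that is not given in the sources used here. Of these 9, 0 were among the 10 listed as lower in all 3 single tables.

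piRNAs, small RNAs of the germ line that bind PIWI proteins, were listed as lower in all 3 Mtdh-/- libraries for 211 sequences and as higher for 14, in the authors' deposited tables. For mmu_piR_009309 (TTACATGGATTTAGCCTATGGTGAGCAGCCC) the authors' deposited tables gave normalized values of 361 and 6217 in wild type 1 and 2, and 394, 103 and 414 in Mtdh-/- 1, 2 and 3. Its sequence matched the annotated transcript of Gm21284, and the other 4 named piRNAs with lower values matched no annotated transcript. Those were mmu_piR_018626 (ACATGATGGTATCGTGGCCTAATTCCCAA), mmu_piR_022403 (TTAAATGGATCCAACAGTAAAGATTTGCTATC), mmu_piR_018225 (TCCCTTGGATCTAGATGCTATTTCATCCC) and mmu_piR_031911 (TGACTGGATCCATCAGTTGGGCACGAAGAC). In the authors' deposited tables they stood at 4, 17.6, 10.5 and 18.2 in wild type 1, at 214, 579, 632 and 375 in wild type 2, and at 0 to 34.2 in Mtdh-/-. Of the 211, wild type 2 lay above wild type 1 for 210, and every Mtdh-/- value lay below both wild-type values for 37. With 10 added, both wild types lay within 2-fold of each other for only 1 of the 211, and for 7 of the 14 listed as higher. A high value in 1 wild-type library raises the mean of both, which by itself favours listing as lower over listing as higher. The numbers 211 and 14 therefore do not by themselves show a loss of piRNAs.

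Of the piRNAs with higher values, mmu_piR_000219 (ACGGGAAACCTCACCCGGCCCGGACAC) stood at 4 and 24 in wild type 1 and 2 and at 113, 77.6 and 135 in Mtdh-/- 1, 2 and 3 in the authors' deposited tables. Its sequence matched 3 annotated genes, Gm42418 in sense and AY036118 and the ribosomal RNA gene CT010467.1 in antisense. These strands are those of the annotation, and whether the sequence is a fragment of ribosomal RNA was not tested. The other named ones were mmu_piR_002643 (TGAGAGGTGTAGAATAAGTGGGAGGCCC), mmu_piR_026606 (TAGAATGCATACTGCAAATAGATAGGAC), mmu_piR_020844 (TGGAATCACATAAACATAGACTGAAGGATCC) and mmu_piR_033479 (TTAAAAATTTTAATACTGGGGACTGAAAA). Their smallest folds over the 3 authors' deposited tables were 2.97, 2.31, 2.30 and 2.30. The authors' deposited table of all 3 Mtdh-/- libraries as a group listed 66 piRNAs as higher, 8 of them among the 14, and the tables of Mtdh-/- 1 with 2, 2 with 3 and 1 with 3 listed 122, 141 and 98. Group tables of lower piRNAs were not analysed here.

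The authors' deposited tables listed 952, 1314 and 361 piRNAs as higher and 768, 1313 and 663 as lower in Mtdh-/- 1, 2 and 3, 4222 in all. Of these, 141 were higher in one library and lower in another. Lists drawn independently from these 4222 would share 25.3 higher and 37.5 lower piRNAs. Lists drawn within classes of the same wild-type values, which keeps the shared controls, would share 26 higher (95% range 18 to 34) and 192 lower (178 to 205), against the observed 14 and 211. Both draws left out piRNAs listed in no table, which raises the expected overlaps, so these are upper limits. The values are the authors' own and listed only for piRNAs past their fold threshold, so they could not be retested, and their depth is unknown.

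**Figure D3:**
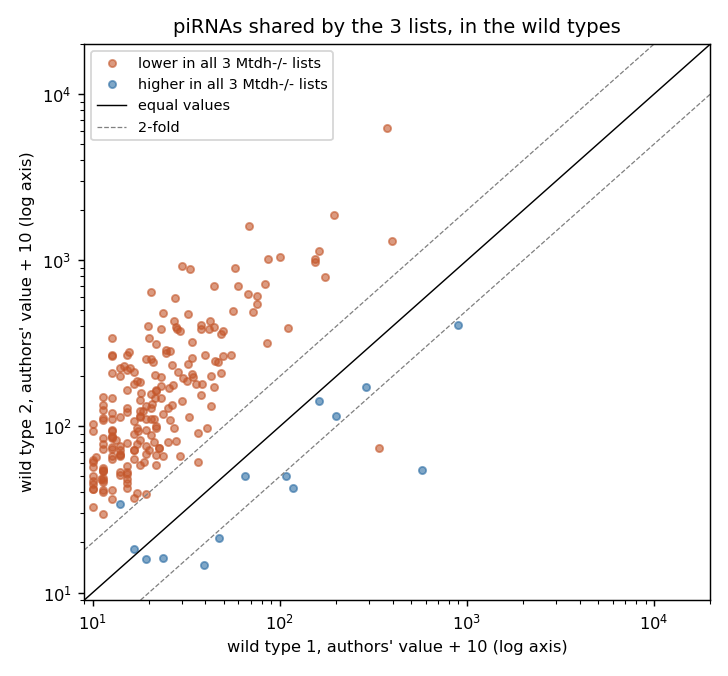
Normalized values, plus the constant the authors added, of the piRNAs that the authors' deposited tables list in 1 direction in all 3 Mtdh-/- libraries, on log axes, with wild type 1 on the x axis, wild type 2 on the y axis and 1 point per piRNA. Of the 211 listed as lower, 210 lay above the line of equal values.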

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

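The tests with counts of the most abundant sequence, with counts of the exact mature sequence and with the block by library similarity were chosen only after the results were seen. Without a filter edgeR called 3 miRNAs higher and 2 lower among 512 (25 at an unadjusted p under 0.05). miR-17-3p, miR-199a-5p and miR-214-3p were higher, and miR-883b-5p and miR-191-3p lower. Their counts were high in only 1 or 2 libraries (miR-883b-5p 4 and 485 in wild type 1 and 2, then 3, 2 and 5; miR-214-3p 8 and 18, then 10, 540 and 17), and the cause was not tested. With all other settings the counts stayed at 0 and 0, with 2 to 19 miRNAs at an unadjusted p under 0.05. Of 1184 values of the 67 named miRNAs under alternatives, 86 had the other sign and 0 passed the threshold.

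The number of lists called was 2, and 0 with the strict filter, 0 with an estimated correlation, 0 with fry, 4 with upper-quartile scaling and 4 at an adjusted p under 0.1. Leaving out 1 library gave 0 to 1 lists. The block by library similarity gave 5 lists, with p-values too small because the block was read from the same counts. The let-7 call held in 13 of 19 settings, with medians of 0.57 to 1.23 when 1 library was left out. The X-linked call held in 10 of 19, with medians of -0.80 to 0.06, and its sign reversed to 0.0617 without wild type 2. Both counts of settings include the fit without the robust option, which cannot change a list test. They also include the block by library similarity, with its too small p-values. Every setting but the estimated correlation and fry kept the preset correlation of 0.01, against an estimate of 0.344 for let-7. With the estimated correlation (camera, adjusted p = 0.528) and with fry (adjusted p = 0.427) both calls were lost. Without a wild-type library the lone other one is assumed to vary like the Mtdh-/- group. Apart from the fewer samples, the cause of these changes was not tested. The median of all log2 fold changes shifted by -0.34 with upper-quartile scaling, -0.14 with library totals, -0.17 with limma, -0.11 without the 10 most abundant, -0.16 without Mtdh-/- 3, and -0.19 and -0.10 with counts of the exact and of the most abundant sequence.

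With the replicate number as a block, 0 miRNAs passed (12 at an unadjusted p under 0.05) and 1 list was called, let-7 (adjusted p = 0.0191 by camera of limma), while the X-linked list was at 0.247. Only Mtdh-/- 3 carried the number 3, so the block absorbed it and the genotype contrast rested on the libraries numbered 1 and 2. The settings in which the let-7 call held include this block. The numbers did not pair the libraries, since deviations of those with the same number correlated at -0.44 and 0.10.

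Of the authors' lists, piRNAs higher in all 3 tables numbered 14, and 0 at 4-fold or more and 178 in at least 2 tables. piRNAs lower in all 3 numbered 211, 43 at 4-fold or more and 605 in at least 2 tables. miRNAs in 1 direction in all 3 numbered 10, 4 at 4-fold or more and 82 in at least 2 tables. The stricter and looser limits by construction list fewer and more. Depth limits mostly Mtdh-/- 2, where 3 counts are 25.3 CPM.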

Other observations

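The tests that read cell types from the wild-type libraries alone, that set miRNAs with ATGG against the others and that used the block by library similarity were chosen only after the result was seen. miR-425-5p stood at 49195 CPM in wild type 1, 661 in wild type 2 and 39480 in Mtdh-/- 3, while miR-425-3p stood at 101, 1299 and 178 CPM in the same libraries. miR-470-5p stood at 6942 and 40405 CPM in wild type 1 and 2, and miR-470-3p at 257 and 14.7 CPM. The piRNAs in the authors' deposited tables had a median length of 30 nt, and 91.4% began with T, the base usual at the start of primary piRNAs. CAGCA occurred in 7.15% of the piRNAs listed as higher in Mtdh-/- 2, against 1.37% and 2.77% of those listed as higher in Mtdh-/- 1 and 3. Among those listed as lower in Mtdh-/- 1, 2 and 3 it occurred in 3.91%, 1.68% and 2.26%. It occurred in 4.13% of listed piRNAs with both wild types within 2-fold. CAGCA was not among the points fixed before the data were examined, and the contrast was not tested on separate data.

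Wild type 1 and Mtdh-/- 3 resembled each other more than the other libraries of their genotypes. Another make-up of cell types would move both arms of a hairpin together if cell types do not differ in which arm they keep, which was not tested. The wild-type difference of the arms had a Spearman rho of -0.32 over 41 hairpins (95% bootstrap interval -0.59 to -0.00226, permutation p = 0.0420). On that assumption this argues against cell types as the main source of the difference between the wild types. Large shifts of single arms, such as -6.69 and 3.14 for the arms of miR-425, could hide a smaller shared one, so a part for cell types is not excluded. Some minor arms had few counts, such as miR-195a-3p at 0 CPM in wild type 1 and 86.3 CPM in wild type 2. Mtdh-/- 3 was not in this test, and hairpins of 1 cluster are not independent. Unequal depth is argued against too, since with all libraries thinned to 118475 counts the correlation with Mtdh-/- 3 still exceeded that with wild type 2 by 0.0805 (0.0698 to 0.0892 over 50 draws). Unequal capture of single mature sequences is a candidate explanation that the same rho of -0.32 leaves open. Independent capture of the arms would not by itself give a negative rho, and no other biological explanation was tested. The 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05, with 0 miRNAs called between genotypes and at most 1 in any other split, that of wild type 1 with Mtdh-/- 3 (42 at an unadjusted p under 0.05, against 7 between genotypes).

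The let-7 family had higher values in Mtdh-/-. Tags shared between isoforms are argued against as its cause, since counts of the exact mature sequence kept 0.873 of the median of the same 9 members. With the block by library similarity 0.818 of the median remained. The median log2 difference was 0.66 between Mtdh-/- 3 and wild type 1 and 0.88 between Mtdh-/- 1 and 2 and wild type 2, while the wild-type libraries differed by 0.73. The block set wild type 1 and Mtdh-/- 3 against the rest. Yet Mtdh-/- 2 correlated no better with wild type 2 (Pearson r = 0.842) than with Mtdh-/- 3 (0.844). For let-7, Mtdh-/- 2 lay a median of 0.63 above the mean of Mtdh-/- 1 and 3. With 1 wild-type library in each part, an effect of Mtdh and a difference between libraries cannot be told apart, and either may underlie the values.

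In 69.2% of the 211 piRNAs listed as lower in all 3 Mtdh-/- libraries the sequence held ATGG, against 18.9% of the other listed piRNAs. ATGG occurred in 47.0% of all listed piRNAs at least 2-fold higher in wild type 2 than in wild type 1, in 10.7% of those at least 2-fold lower and in 13.3% of the rest. ATGG was itself picked after these lists were seen, so these shares describe the lists and are not a test. Lists drawn within classes of the same wild-type values shared 0.910 of the observed number (0.844 to 0.972), an upper limit because only listed piRNAs could be drawn, so how much of the overlap comes from the shared controls and the high values of wild type 2 stays open. Capture in wild type 2 that favoured ATGG stays open, since the 20 miRNAs with ATGG were too few to decide it: against the other libraries they lay 0.19 higher on the log2 scale than miRNAs without it in wild type 2 (95% bootstrap interval -0.32 to 0.99, permutation p = 0.371), and by the same measure at 0.15, -0.26, 0.21 and -0.13 in wild type 1 and Mtdh-/- 1, 2 and 3, so the value was not particular to wild type 2. A difference of genotype stays among the open explanations, and it was not tested for these piRNAs.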
